A study of Mus musculus with 2 samples.

How the data were processed

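ATAC-seq marks open chromatin by letting a transposase insert sequencing adapters where DNA is accessible. It was applied to stomach tissue of mouse embryos at embryonic day 16.5, from strain B6NCrl, with embryos of both sexes pooled. There was 1 group with 2 biological replicates, and the labels give the group and the replicate numbers. With 1 group, no conditions could be compared and no test across replicates could be made, so reproducibility and the make-up of the accessible regions were described.

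Per the file headers and the labels, the deposited files are peak lists on mm10. There is a list for each replicate, called on pseudoreplicates of that replicate, and there are lists of the pooled reads and of peaks that overlapped between replicates (called the replicated list here). A region of the replicated list need not be in both replicates' own lists, and some promoter regions of listed genes were in neither. For each there are lists thresholded or ranked by the irreproducible discovery rate (IDR), of which the conservative list comes from the true replicates. Each peak carries a signal value, a summit and −log10 values of p and q, all deposited by the authors, and the ranked lists carry a −log10 IDR deposited by the authors. The ranked list of the true replicates also holds a deposited −log10 p for each replicate, in columns not named by replicate. The peak caller, its version, the aligner and the IDR threshold are not given in the sources used here. Read depth is not given either, so no counting error of the peaks themselves could be stated. Signal values are the authors' own and were used only to rank and describe peaks within a list.

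Overlapping peaks of a list were merged into regions, with the highest signal and its summit kept for each region. The genome was GRCm38.p6, the same build as mm10, with GENCODE vM21 genes. All 21 chromosomes named in the filtered lists were in it, 0 peaks ended beyond a chromosome, and 990 of 990 start codons checked on chromosome 19 read ATG. A promoter region lay within 1 kb of a TSS of any transcript of 1 of 21938 protein-coding genes, and a distal region lay over 1 kb from the TSS of every annotated gene. Promoter CpG content is the observed over expected ratio.

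Shares of overlapping regions used a minimum of 1 bp, with 20 shuffles within chromosomes as background and Wilson 95% intervals, which cover counting of regions only. The 26 gene lists were compared with all other protein-coding genes by a two-sided Fisher's exact test. The median number of distal regions within 50 kb of the gene body was compared with 10000 random lists matched on gene length and gene density (two-sided permutation p). For 29 motifs, the window within 100 bp of the summit was compared with flanks at 600 to 700 bp of the same region by an exact binomial test of discordant regions. Each motif was also read backwards, without complementing it, as a control for base composition. Reading a motif backwards keeps its base content but not its CpG content. Intervals of folds come from 1000 bootstrap draws over regions, with 0.5 added to each sum. The sequence of the highest regions was compared with the mitochondrial genome by blastn, at 90% identity or more, a comparison chosen after the data had been seen. The same search was used for peaks absent from the conservative list, where a match covered at least 50% of a peak's length, and their repeat-masked share was taken from the lower-case bases of the genome. For recovery by gene list, replicate 1's regions near the genes of a list were compared with random regions of the same signal class (20 classes) and promoter class, and, after the data had been seen, with random lists of genes matched on the number of nearby regions. The smallest p that the 10000 draws can give is 0.0002. Adjusted p-values are Benjamini-Hochberg values over the 26 lists or the 29 motifs. Genes and regions are not replicates, so these tests compare lists or windows within this tissue.

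Gene lists, motifs, tests and most alternatives were fixed before the data were examined. The alternatives were the overlap rule, the peak list, −log10 q of at least 5 or 10, the promoter window (500 bp or 2 kb), the distal window (20 or 100 kb), the motif window and flank, CpG-matched random lists, and each replicate's own list. Further alternatives were added after the data had been seen: the correlation of signal between overlapping regions of the replicates' own lists, promoters taken only at the 5′ end of each gene, and distal counts with Fgfr2 left out. Gene signals, and statements that a gene had no region, are for the replicated list unless another is named. Genes were named by a fixed rule: per list, the 4 members with the highest promoter signal and up to 3 members without a promoter region, in alphabetical order. All Hox members, and members with a promoter region in lists of lineages thought silent in stomach, could also be named. Genome-wide, the 20 genes with most distal regions and the 10 highest regions outside and inside promoters could be named. Ahsp (erythroid list) and Amy2b (pancreas list) matched no protein-coding gene. Genes that stand in 2 lists are Pdx1, Krt19, Isl1, Hand2, Tbx3, Tcf21, Gli1, Gli2, Ptch1 and Bmp4.

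On simulated data, the Fisher test called 48.1% of lists whose odds were raised by a factor of 8 and 97.5% of lists lowered by that factor, against 1.36% of unchanged lists, so a list that was not called higher may still be. The distal test called 41.7% of lists whose counts were doubled plus 1, and 0 of 42 unchanged lists. All 6 motifs planted in 5% of sequences were called, as were 8.70% of the 23 motifs not planted, and 0 of 29 motifs were called with none planted. The simulated sequence was random, with equal base composition at summits and flanks. These motif rates therefore do not cover false calls from a difference in composition. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, matplotlib 3.10.9 and blastn 2.17.0 were used.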

Results

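Open chromatin was mapped in the stomach of mouse embryos at embryonic day 16.5 in 2 biological replicates, each a pool of embryos. The replicated list held 97533 peaks in 55654 separate regions that covered 33.5 Mb. Replicate 1's own list held 107512 peaks in 66592 regions and replicate 2's own list held 54416 peaks in 37414 regions.

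The first question was how well the replicates matched. Of replicate 2's regions, 80.7% overlapped a region of replicate 1 (95% interval 80.3 to 81.1), and 43.3% of replicate 1's regions overlapped a region of replicate 2 (42.9 to 43.7). Shuffled regions gave 2.66% and 1.51%. The highest-signal regions were shared almost completely: 99.7% of the top decile of replicate 1 and 100% of the top decile of replicate 2 overlapped the other list, against 9.43% and 43.1% of the lowest deciles. The replicates' own IDR lists held 48308 and 24327 peaks, a self-consistency ratio of 1.99. The pooled and conservative IDR lists held 53843 and 42567 peaks, a rescue ratio of 1.26. Across 99700 peaks of the ranked list, log2 of the −log10 p values of the replicates correlated with Pearson's r of 0.733 and Spearman's rho of 0.625; peaks are not independent replicates. Over the 53706 distal peaks the values were 0.579 and 0.470.

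**Figure D1:**
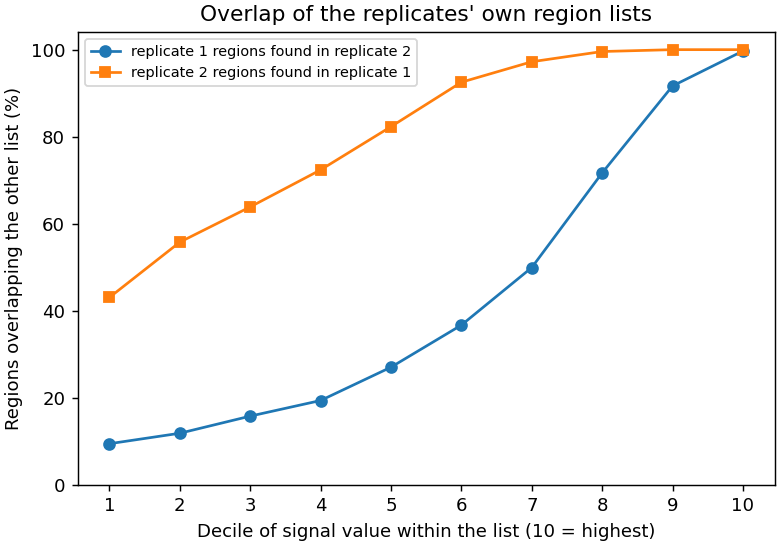
Share of each replicate's own regions (y axis, %) that overlapped the other replicate's list, by decile of signal value within the list (x axis, 10 is highest). Lines join the deciles; recovery of replicate 1 regions went from 9.43% in the lowest decile to 99.7% in the highest.

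The second question was where accessible regions lay. Promoters held 31.9% of the replicated regions, introns 34.6% and intergenic sequence 28.9%, while random windows of the same widths fell in promoters in 5.05% of cases, in introns in 40.9% and in intergenic sequence in 50.2%. Promoter regions were wider, with a median of 861 bp against 420 bp in introns, and had a median signal of 7.85 against 3.82. The promoter share in the replicates' own lists was 34.8% ± 8.88 (SD, n = 2), with 28.5% in replicate 1 and 41.0% in replicate 2. It rose to 63.4% in the conservative IDR list. Distal regions numbered 35405, or 63.6% of the replicated regions.

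Of 21938 protein-coding genes, 66.8% had an accessible promoter, from 9.94% in the lowest decile of promoter CpG content to 98.7% in the highest. Of the lists that mark stomach epithelium and muscle, 3 were called higher than other genes. All 20 stomach epithelial transcription factors had a promoter region (adjusted p = 0.00408, two-sided Fisher's exact test), 20 of them in replicate 1's list and 18 in replicate 2's. Among them Klf5, a factor of epithelial progenitors, had a signal of 14.2 at chromosome 14, 99298230 to 99299469, and Sox2, a regulator of foregut fate, had 10.8. Sox21 had 12.1, and Foxa3 had 10.8 in a region shared with the promoter of Sympk. Of the 18 epithelial junction and keratin genes, 17 had a promoter region (adjusted p = 0.0310, Fisher's exact test), among them Cdh1, the epithelial cadherin, with 10.1, and Cldn18, a tight junction gene of stomach and lung, with 9.57. Tjp3 had 9.49 in a region it shared with Pip5k1c, St14 had 9.44, and Prss8 had none. Of the 18 smooth muscle genes, 17 had one (adjusted p = 0.0310, Fisher's exact test). Acta2, smooth muscle actin, had a signal of 10.8 at chromosome 19, 34255164 to 34255751, Myl9 had 10.6, Mylk 10.1 and Tpm1 10.1, the last at an internal TSS, and Ldb3 had none. These 3 lists also exceeded random lists of matched CpG content, at medians of 80%, 66.7% and 61.1% (adjusted permutation p = 0.0208, 0.0267 and 0.00780). The matching used CpG content at the 5′ end of the gene, while a region at any TSS counted. With promoters taken only at the 5′ end of the gene, the epithelial junction list no longer passed Fisher's exact test (16 of 18, adjusted p = 0.0555). By Fisher's exact test the smooth muscle list did not pass with windows of 500 bp or 2 kb (adjusted p = 0.0902 and 0.0557), in the optimal IDR list (0.0538) or at −log10 q of at least 10 (0.0562), and the stomach factors did not pass in the conservative IDR list (0.0950).

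Regulators of gut mesenchyme had a promoter region in 21 of 22 genes (adjusted p = 0.0130, Fisher's exact test), with Isl1 at 12.4, Tbx3 at 12.3, Pitx2 at 9.76 at an internal TSS and Meis1 at 9.36; Hand1 had none. Signalling genes of the Hedgehog, Wnt, BMP and Notch pathways had one in 32 of 34 (adjusted p = 0.00408, Fisher's exact test), led by Hey2 at 17.6, Smo at 12.2, Hey1 at 11.8 and Grem2 at 11.5, with none at Bmp5 and Shh. Housekeeping genes had one in 20 of 20 (adjusted p = 0.00408, Fisher's exact test), with Psmb2 at 16.9, Rplp0 at 16.1, B2m at 15.6 and Eef1a1 at 15.3. None of these 3 lists was called higher than lists of matched CpG content (adjusted permutation p = 0.628, 0.548 and 0.136). The medians of those matched lists were 90.9%, 88.2% and 85%, which left little room above them. By Fisher's exact test, the mesenchyme list did not pass with 5′ ends alone (adjusted p = 0.0555).

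Of the lists of other organs and cell types, 4 were called lower than other genes. Promoter regions were found at 5 of 18 germ cell genes (adjusted p = 0.00522), 6 of 18 skeletal muscle genes (0.0192), 5 of 16 liver genes (0.0202) and 6 of 16 photoreceptor genes (0.0440), each by Fisher's exact test. Alb, Afp and Ahsg of liver had none. Of these 4 lists only the germ cell list was called lower than lists of matched CpG content (27.8% against 66.7%, adjusted permutation p = 0.00260). Liver, skeletal muscle and photoreceptor genes were not called (adjusted permutation p = 0.821, 0.257 and 0.821). They stood at 31.25% against 37.5%, 33.3% against 50% and 37.5% against 43.75%. By Fisher's exact test, the skeletal muscle list passed in neither replicate's own list (adjusted p = 0.0907 and 0.126), and the photoreceptor list did not pass in replicate 2's (0.110) or at −log10 q of at least 5 (0.0680). The skeletal muscle list did not pass in the pooled list either (0.213), nor the liver list with a 2 kb promoter window (0.126). Several of the promoter regions in these lists were shared with another gene or lay at an internal TSS: Apoh shared its region with Prkca, Actn3 with Zdhhc24, Mylpf with Tbc1d10b, Ckm with Klc3 and Rom1 with Eml3, and that of Abca4 lay 77558 bp from the 5′ end of the gene. Others were not shared and lay within 1 kb of the 5′ end, in both replicates' own lists: Opn1sw, a photoreceptor gene, had a signal of 12.3, Tnni2 and Mymk of skeletal muscle had 6.40 and 4.11, and F2 of liver had 6.03. Dazl, a germ cell gene, had a signal of 12.8 and was in both replicates' own lists.

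**Figure D2:**
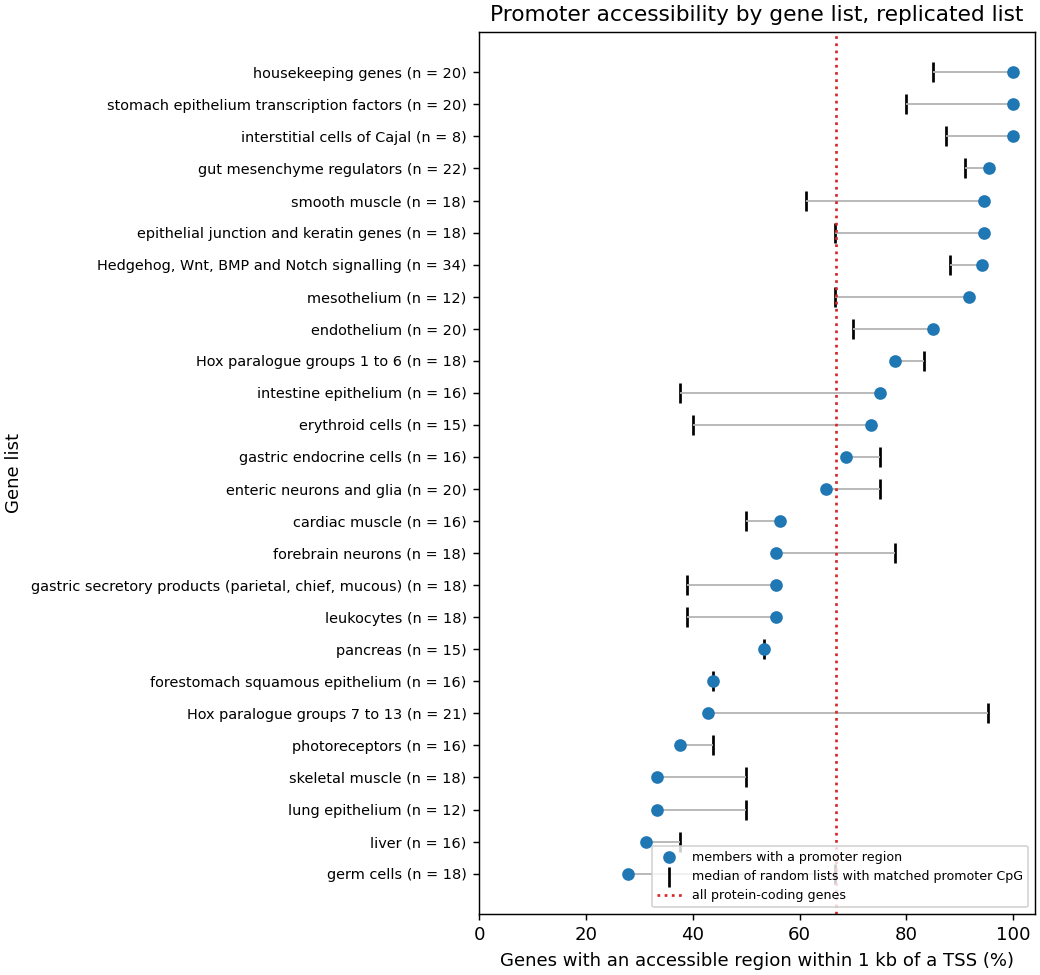
Share of the genes of each list (y axis) with an accessible region within 1 kb of a TSS in the replicated list (x axis, %). Dots are the lists, black bars the medians of random lists with matched promoter CpG content and the dotted line all protein-coding genes at 66.8%; Hox paralogue groups 7 to 13 stood at 42.9% against 95.2%.

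The Hox genes lay out position along the body axis. A promoter region was found at 14 of 18 genes of groups 1 to 6 and at 9 of 21 genes of groups 7 to 13. With 5′ ends alone the counts were 9 of 18 and 8 of 21, since 5 of the 14 regions of groups 1 to 6 lay over 1 kb from the 5′ end of the gene. Hoxa5 had the highest signal of either list, 8.08, followed by Hoxa1 at 6.81, Hoxc6 at 6.19 and Hoxa4 at 5.95. In groups 7 to 13 the highest was Hoxb7 at 5.56, and Hoxb9, Hoxa7 and Hoxd11 had 5.10, 3.94 and 3.80, while Hoxa9, Hoxc8, Hoxc9, Hoxc10 and Hoxd9 had no region. Groups 7 to 13 did not pass the Fisher's exact test (adjusted p = 0.0728), but stood below lists of matched CpG content, 42.9% against 95.2% (adjusted permutation p = 0.00260). Groups 1 to 6 stood at 77.8% against 83.3% (adjusted permutation p = 1). Of the 18 genes of groups 1 to 6, 14 had a region in replicate 1's own list and 9 in replicate 2's. Of the 21 genes of groups 7 to 13, 12 had a region in replicate 1's own list and 3 in replicate 2's. By Fisher's exact test they did not pass in replicate 1's list (adjusted p = 0.412), in the pooled list (0.377), with a 2 kb window (0.126) or with 5′ ends alone (0.0793). They passed as lower in replicate 2's list (0.000216), in the optimal and conservative IDR lists (5.29e-05 and 1.96e-06), at −log10 q of at least 5 and 10 (0.0140 and 7.70e-05) and with a 500 bp window (0.0279). The difference between the Hox lists was not tested.

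No other list passed the Fisher's exact test in the replicated list. In the optimal IDR list, gastric secretory, forestomach squamous, endocrine, leukocyte and forebrain lists stood lower (adjusted p = 0.0244, 0.00445, 0.0171, 0.000368 and 0.00609, Fisher's exact test). In the conservative IDR list they did too (0.0173, 0.0144, 0.0353, 0.000291 and 0.0173, Fisher's exact test). Pancreas and cardiac muscle also stood lower there (0.0176 and 0.0144, Fisher's exact test). In replicate 2's own list gastric secretory products, leukocytes and cardiac muscle stood lower (adjusted p = 0.0225, 0.00127 and 0.0419, Fisher's exact test), and in replicate 1's own list mesothelium stood higher (0.0327). With 5′ ends alone, leukocytes and lung epithelium stood lower (adjusted p = 0.0179 and 0.0377, Fisher's exact test). Leukocytes also stood lower at −log10 q of at least 10 (0.00323), and lung epithelium in the pooled list (0.0287), by Fisher's exact test. Of gastric secretory products, 10 of 18 genes had a region, with 13 in replicate 1's own list and 5 in replicate 2's. Ctse had 7.89 at an internal TSS, Tff2 had 6.89 and was in replicate 1's own list but not in replicate 2's, and Cckbr had 6.61, and Atp4b, Chia1 and Gkn1 had none. Atp4a, a subunit of the gastric proton pump, had 14.2, but that region lay 4820 bp from the 5′ end of the gene. Of forestomach squamous genes 7 of 16 had a region, with Perp at 10.7 and none at Dsg3, Ivl and Krt13. Of gastric endocrine genes 11 of 16 had one, with Chgb at 12.2 and none at Gast, Ghrl and Neurog3. In replicate 1's own list 10 endocrine genes had one, and 6 in replicate 2's. For interstitial cells of Cajal, the pacemaker cells of the gut, it was 8 of 8, with Etv1 at 11.3 and Kit at 8.69. Enteric neurons and glia had 13 of 20, with Snap25 at 10.6 and Ret at 7.58 and none at Ascl1, Elavl3 and Foxd3; they had 17 of 20 in replicate 1's own list and 10 in replicate 2's, and passed as higher in the pooled list (adjusted p = 0.0247, Fisher's exact test). Endothelium had 17 of 20, with Kdr at 8.03 and none at Emcn, Pecam1 and Tek, and had 16 in replicate 1's own list and 11 in replicate 2's. Leukocytes had 10 of 18, with 9 in replicate 1's own list and 3 in replicate 2's. Mesothelium had 11 of 12, with 12 in replicate 1's own list and 7 in replicate 2's. Pancreas had 8 of 15, lung epithelium 4 of 12, forebrain neurons 10 of 18 and cardiac muscle 9 of 16. Erythroid genes had 11 of 15 and intestinal epithelial genes 12 of 16, and both exceeded lists of matched CpG content, at medians of 40% and 37.5% (adjusted permutation p = 0.0135 and 0.00780). Neither passed Fisher's exact test (0.850 and 0.681), and in the conservative IDR list the intestinal list turned lower (log2 odds ratio −2.19, adjusted p = 0.0144, Fisher's exact test). Tfrc had 16.1, Nfe2 12.8 and Klf1 8.41, and Gpa33, Vil1 and Lgals4 had 6.97, 6.01 and 5.79. Of the 16 intestinal genes, 8 had a region in replicate 1's own list and 8 in replicate 2's.

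Distal regions were more frequent around 4 lists than around genes of matched length and density. Gut mesenchyme regulators had a median of 4.5 distal regions within 50 kb against 1 in random lists (adjusted permutation p = 0.00520). In the own lists of replicates 1 and 2 their medians were 5 against 1.5 and 2 against 1. Epithelial junction and keratin genes had 5.5 against 2 (0.00520), stomach epithelial transcription factors 5 against 1.5 (0.00693) and smooth muscle genes 5.5 against 2 (0.0312). Cdh1 had 18 distal regions and Mylk had 17. Some neighbouring genes of the epithelial junction and mesenchyme lists had overlapping windows, so their counts are not independent. The random lists were not matched for such neighbours. No list stood lower, at an adjusted or an unadjusted p under 0.05, but this test could hardly call one. A median count cannot fall below 0. The low tail of the random medians already reached 0 for lists such as gut mesenchyme, lung epithelium and Hox groups 7 to 13. It lay no higher than 1 for any list. Whether any list had fewer distal regions therefore cannot be told from these medians. Only the mesenchyme list passed in replicate 1's own list, and only the 2 epithelial lists in replicate 2's. The smooth muscle list passed in neither (adjusted permutation p = 0.0901 and 0.107). It did not pass with windows of 20 or 100 kb (0.186 and 0.0637), in the optimal or conservative IDR lists (1 and 0.495) or at −log10 q of at least 10 (0.121) either. The epithelial junction list did not pass at −log10 q of at least 10 (0.0520), the stomach factors did not pass at 100 kb or by the mean (0.0637 and 0.0801), and the mesenchyme list did not pass in the optimal or conservative IDR lists (0.384 and 0.104). The signalling list passed as higher by the mean (0.0416), in the pooled list (0.0433) and in the optimal IDR list (0.0156), and the intestinal list in the pooled list (0.0433). With Fgfr2 left out of the signalling list, which ended all 3 of its calls (0.0801, 0.174 and 1), no list passed by the mean, and 1 each passed in the pooled and optimal IDR lists, while 4 lists passed by the median in the replicated list. The signalling calls in the pooled and optimal IDR lists used medians, and how high the count of Fgfr2 was does not set a median. Across the genome the median gene had 2 distal regions. Genes with most were long, such as Gse1 (353 kb) with 44, Lrmda with 35, Rad51b with 35 and Nav2 with 33. Gm20388 with 245 and Fgfr2 with 105 have annotated spans of 4435 and 2961 kb.

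At distal summits, 17 of 29 motifs were enriched over the flanks and 9 were depleted (largest adjusted p = 0.0105 and 0.0362, exact binomial test). The motif of CTCF, an insulator protein, was found at 3.29% of summits, 18.8-fold over flanks (95% interval 14.7 to 24.5). That of AP-1 stood at 11.6% (3.02-fold, 2.85 to 3.21), the CAGCTG E-box at 23.6% (2.27-fold) and TEAD at 8.25% (1.68-fold). HNF1 was enriched 8.06-fold at 0.387% of summits, HNF4 2.24-fold, GRHL 1.61-fold and FOX 1.40-fold. KLF and SP sites were enriched 5.15-fold, while their reversed motif was itself enriched 2.58-fold. The CArG box of SRF, a regulator of smooth muscle genes, was enriched 1.31-fold. The depleted motifs were PHOX2 (0.172-fold), ONECUT (0.509), TAATTA (0.515), MEF2 (0.579), NR5/ESRR (0.633), NKX (0.819), GATA, CDX (0.895) and TCF/LEF (0.919). GATA sites were found at 27.2% of summits and 30.6% of flanks, a fold of 0.889. The reversed motifs of 4 depleted motifs were lower still beyond the 95% interval: 0.690 for GATA, 0.317 for MEF2, 0.593 for NKX and 0.688 for CDX. Of the 9, only TAATTA fell below its reversed motif (0.636) beyond the 95% interval. The CDX call ended in both IDR lists and at −log10 q of at least 5 and 10, that of PHOX2 in both IDR lists, that of TCF/LEF in the optimal IDR list and those of NKX and SOX in the conservative one. SOX sites (1.13-fold) did not exceed their reversed motif (1.15-fold). AP-1 had folds of 3.18 and 2.77 in the own lists of replicates 1 and 2, FOX 1.47 and 1.27, and HNF1 7.90 and 4.57. At promoter summits NRF1, YY1 and NFY were enriched 25.1-fold, 12.9-fold and 3.34-fold, and FOX stood at 0.595, above its reversed motif at 0.359. The reversed motif of NFY stood at 0.826. Those of NRF1 and YY1 were found at 0.00563% and 0.0113% of promoter summits, too few to control for composition, and YY1 did not exceed its own beyond the 95% interval.

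**Figure D3:**
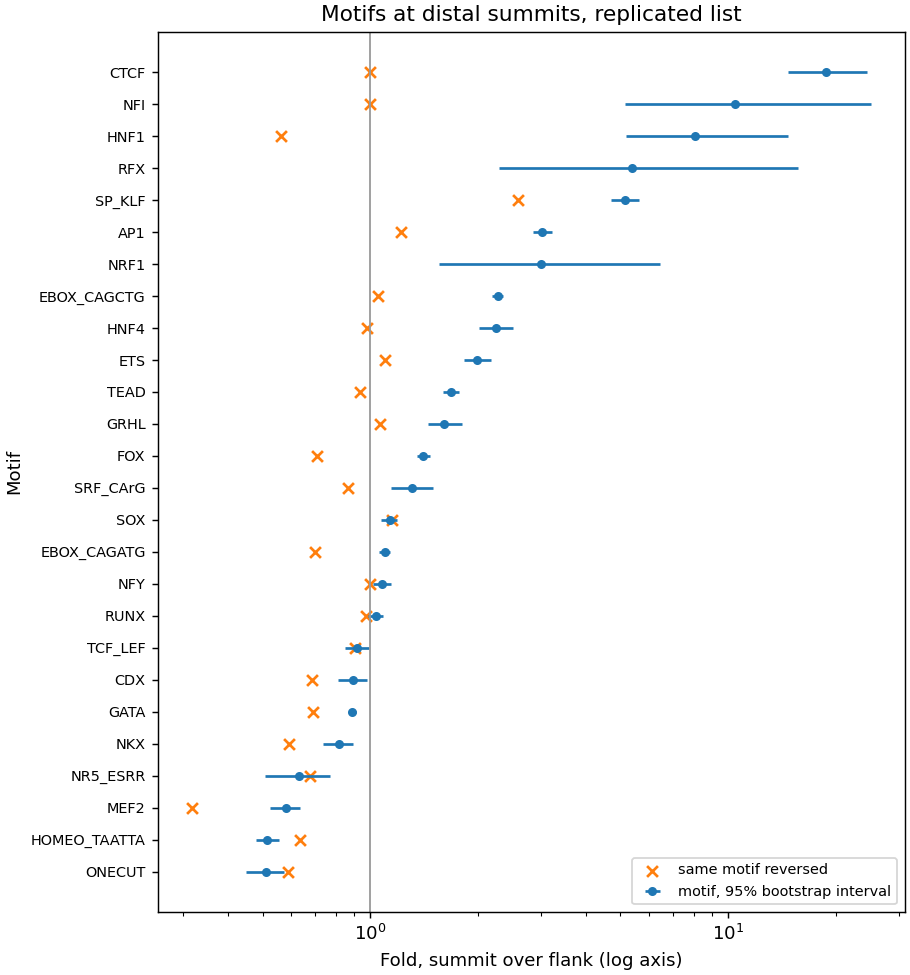
Fold of each motif (y axis) at distal summits over flanks (x axis, log scale) in the replicated list, for motifs found at 20 or more summits. Dots are folds with 95% bootstrap intervals and crosses are the reversed motifs, to which the minimum of 20 summits was not applied. CTCF was highest at 18.8. Its reversed motif, with a fold of 1, was found at 0.00282% of summits, too few to control for composition.

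The highest signals outside promoters included sequence that matches the mitochondrial genome. The highest, 53.8, was on chromosome X at 143482937 to 143483180, in intergenic sequence 35531 bp from the nearest TSS, of Pak3, and had no such match. The second, 50.5, was on chromosome 2 at 69355469 to 69355735 near Abcb11, and 48.3% of its length matched mitochondrial DNA at 90% identity or more. Regions whose nearest TSS was of Gm5426, G6pd2, Galc and Nxph1 matched over 86.7%, 89.6%, 74.6% and 90.1% of their length. In promoters the highest were at Tmem218 with 26.4, Kifap3 with 25.7 and Cbwd1 with 25.7, and none of the 10 highest had a mitochondrial match.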

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

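Tests chosen only after the result was seen are the mitochondrial matches and repeat-masked shares over separate regions, the repeat of the recovery test with 10000 draws, the recovery test against random lists of genes, and the 0.5 added to bootstrap sums in the motif intervals.

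In the ranked list of the true replicates, which the comparisons used only for the correlation, 199 peaks passed an IDR of 0.05 but were absent from the conservative list. They stand out as a signal in data outside the main measurement. Of these, 61 lay on scaffolds that belong to no assembled chromosome and 138 on assembled chromosomes, where they overlapped no region of the pooled list. The strongest, with a signal of 49.2, was on chromosome 9 at 24541943 to 24542230. Nuclear copies of mitochondrial DNA were tested as an explanation: 10.1% of the 138 peaks matched the mitochondrial genome over at least 50% of their length, far from the share over 50% set for a cause and just above the 10% set to exclude it. However, these 14 peaks all lay in 1 region, on chromosome 1 at 24611586 to 24616170, and the other 124 had no mitochondrial match. Over separate regions the share was 1 of 60, or 1.67% (95% interval 0.295 to 8.86), which excludes such copies as the explanation of the set and leaves them open for that region. Repeated sequence was tested next: their median repeat-masked share was 19.3%, against 6.67% in kept peaks and 21.5% at the 95th percentile of kept peaks. That value lies between the bounds set. Over the 60 separate regions the median was 33.1% (95% bootstrap interval 19.3 to 52.2), and the 95th percentile of kept regions was 23.1%, inside that interval; 36 of the 60 lay above it. Repeated sequence may account for part of the set and stays open, as does removal by a list of excluded regions, which the sources used here do not describe; no biological explanation was tested.

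Replicate 2's own list was shorter than replicate 1's, 37414 regions against 66592. Recovery of replicate 1 regions rose with signal, to 99.7% in the top decile. This met the bound set for fewer reads or weaker enrichment in replicate 2, which stays possible. Other causes of a shorter list could also spare the strongest regions, so this rise cannot tell them apart. At equal list lengths 65.4% of replicate 1's regions and 69.5% of replicate 2's overlapped the other list. The bound set beforehand for a different cell mixture in replicate 2 was met by the erythroid list. The bound of a second comparison, chosen after the result was seen, was not met, so a different mixture stays open. At matched signal and promoter class 62.2% of replicate 1 regions near erythroid genes were recovered against 50.5% expected. That is a difference of 11.7 percentage points (adjusted permutation p = 0.0208 at 10000 draws of single regions and 0.0433 at 2000). Epithelial junction and keratin genes passed too, with 61.3% against 52.5%, or 8.88 points (adjusted permutation p = 0.0208 and 0.0433). Stomach epithelial factors differed by 7.94 points (0.0520 and 0.0433) and pancreas genes by 10.3 points (0.0910 and 0.0715). However, recovery exceeded the expectation in 20 of the 26 lists, with a median difference of 2.41 points, and regions near 1 gene are not independent. Against random lists of genes with similar numbers of nearby regions, the erythroid difference was 12.4 points against a median of 2.31, or 10.1 points more, with an adjusted permutation p of 0.156. No list passed in that comparison, and 4 had an unadjusted p under 0.05.

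The motifs enriched at distal summits could reflect the base composition of summits. Of the 17 enriched motifs, 15 (88.2%) exceeded the fold of their reversed motif beyond the 95% interval, between the bounds set for and against that explanation, so composition is not excluded for the set. Reading backwards does not keep CpG content, and several long motifs had very few reversed matches. Those of RFX and NRF1, which are among the 15, had none at summits, so for such motifs the comparison says little about composition. No biological explanation was tested here, as there is only 1 group.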

How the results depend on the processing

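The correlation from the replicates' own lists, promoters at 5′ ends and distal counts without Fgfr2 were tried only after the data had been seen. No paired analysis was possible because there is 1 group. For every value in this part the cause was not tested beyond what the alternative itself changes. Depth is unknown, so regions missing from a list cannot be read as closed.

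The share of replicate 1 regions found in replicate 2 was 42.9% with overlap of 50% of the shorter region, 34.5% with reciprocal overlap, 37.7% and 36.6% at −log10 q of at least 5 and 10, 51.7% in the IDR lists and 65.4% at equal list lengths. The reverse share was 80.02%, 61.5%, 96.9%, 99.5%, 97.4% and 69.5%. Counted in regions, the self-consistency ratio was 1.84 and the rescue ratio 1.37. Without IDR the rescue ratio was 1.21 in peaks and 1.29 in regions. Pearson's r was 0.671 in peaks passing IDR, 0.579 in distal peaks, 0.833 on the raw scale and 0.853 for signal in the own lists, and Spearman's rho was 0.668, 0.470 and 0.837 for the first, second and last. The promoter share was 52.6% and 63.4% in the optimal and conservative IDR lists, 41.9% at −log10 q of at least 10, and 28.5% to 41.0% in the lists of single replicates.

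Lists lower at promoters numbered 4, but 10 and 13 in the optimal and conservative IDR lists and 2 at matched CpG content. Lists with more distal regions numbered 4, with 6 in the pooled list, but 2 with the 100 kb window, 2 in the conservative IDR list, 2 at −log10 q of at least 10, and 1 to 2 in single replicates' lists. With Fgfr2 left out they numbered 4 in the replicated list, 0 by the mean, 1 in the pooled list and 1 in the optimal IDR list; adjustment over the lists moved with the signalling list's p. Reversals of log2 odds were enteric neurons and glia in the pooled list (2.56, called higher), gastric endocrine genes in the optimal and conservative lists (-1.98 and -1.72) and intestinal genes in the conservative list (-2.19). At promoters, 10 motifs were enriched and 14 depleted. Folds fell below 1 for FOX (0.595), SOX (0.712), HNF4 (0.885), TEAD (0.875), SRF (0.869), RUNX (0.708), CAGATG (0.621) and GRHL (0.833). Of these, HNF4, SRF and GRHL were not called depleted. Their bootstrap intervals included 1 (0.730 to 1.08, 0.705 to 1.06 and 0.697 to 1.004). RUNX, at 1.03, had not been called at distal summits. FOX, TEAD, SRF, RUNX and CAGATG stood above their reversed motifs (0.359, 0.733, 0.497, 0.626 and 0.525) beyond the bootstrap interval. SOX, HNF4 and GRHL did not differ from theirs beyond it. CAGATG also fell below 1 at distal summits of the optimal (0.980) and conservative (0.960) lists.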

Other observations

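Accessible regions were sparse on the sex chromosomes: 5.45 per Mb on X and 0.174 per Mb on Y (16 regions). Autosomes ranged from 16.8 per Mb on chromosome 14 to 32.1 per Mb on chromosome 11. These densities use the full chromosome length, without correction for mappable sequence or chromosome copies in pools of both sexes. The cause was not tested. Some genes of lists of other organs had promoter regions in the replicated list and in both replicates' own lists. In the pancreas list, Mafa had a signal of 16.7 on chromosome 15 at 75747938 to 75748714, and Nkx6-1 had 14.5, while Ctrb1, Gcg and Iapp had none. In the forebrain list, Dlx1 had 7.28 and Foxg1 4.97, both under the median of 7.85 for promoter regions. Emx1, Emx2 and Fezf2 had none in the replicated list, though Emx1 had a region in replicate 1's own list and Emx2 in both own lists.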
